A study of Homo sapiens with 12 samples.

How the data were processed

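Total RNA of 12 cultures of H9 cells was measured, 1 Illumina bead array each, in 6 groups of 2: dox-minus and dox-plus LHX2 cells at day 4 and at day 16, and shLHX2 and shLuc cells after 12 days of neural induction. Groups were taken from the sample labels, and replicate numbers from the sample titles. The series text states that all samples were biological duplicates and that samples were collected 1 and 13 days after 3 days of doxycycline. Biotinylated cRNA was prepared with an Ambion MessageAmp kit, per the labels' protocols.

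The deposited file of each array gives the mean bead intensity of each probe (AVG_Signal) and a detection p-value, per the file headers. The values show no normalization between arrays: the array medians run from 73.1 to 89.2, and no signal is negative. Whether a background was subtracted, and with which scanner software, is not given in the sources used here. The deposited series value table holds the same intensity values, equal within 0.051, for 10 of 12 arrays. In that table the columns of the 2 shLuc arrays hold each other's values, which affects only their replicate numbers. The per-array files were used. No slide or scan is named in the files. The files name no genome build, and no coordinates are given.

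Probes were matched by Entrez gene identifier to current gene symbols. Of 47227 probes, 3270 carried no identifier, 35670 matched and 8287 kept the name in the file. Signals were background-corrected with the normexp model of limma 3.58.1 in R 4.3.3 (neqc, with the negative-control mean and spread inferred from the detection p-values, offset 16), quantile normalized and put on the log2 scale. A probe was kept if its detection p was under 0.01 on both arrays of at least 1 group, which left 21526 probes, 807 of them without a gene. Each of 15650 genes was represented by its kept probe with the highest mean, and 4013 genes had several kept probes. Detection of a gene was judged on that probe alone. LHX2 has 1 probe, near the 3′ end of its transcript.

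One limma fit held all 12 arrays with a mean per group, 6 residual degrees of freedom and a prior of 5.93 degrees. From it came dox-plus against dox-minus at each day, shLHX2 against shLuc, dox-minus day 16 against day 4, and the difference of the dox effects between the days. Moderated tests were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. With 2 arrays a group, an array left out leaves a lone array that is assumed to vary like the other groups. Replicate numbers were not used as pairs. The differences between replicates of same-numbered arrays correlated across genes at 0.33 for the day 4 dox groups, -0.58 for those of day 16 and 0.07 for the knockdown pair, and not every pair was above 0.1. The highest correlation of any groups was 0.64, between dox-plus day 4 and dox-minus day 16. Between dox-plus day 4 and dox-plus day 16 it was -0.42. What these correlations stem from was not tested.

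The 23 gene lists, of which 22 had at least 4 tested members, cover pluripotency, neural progenitor, forebrain and eye field, cortical hem and choroid plexus, retinal pigment epithelium, midbrain, hindbrain and spinal, neuron, neural crest and placode, mesendoderm and mesoderm, endoderm, surface ectoderm and trophoblast, mesenchyme and fibroblast, BMP targets, Nodal and activin targets, WNT targets, secreted BMP, WNT and Nodal antagonists, Notch pathway, FGF feedback, proliferation, interferon response, stress kinase, amino acid and p53 response, hypoxia, and immediate early genes. Lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Overlaps of calls were set against the product of the call rates and tested with Fisher's exact test per direction.

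The genes named are LHX2, PAX6 and CER1 in every comparison, the 8 called genes with the highest and the 8 with the lowest log2 fold change (6 and 6 for the difference), up to 4 called members of each list, and the 6 leading genes of each overlap. Where a list had no called member, its member with the largest change is named. A few genes that this rule names are not reported here, and they stay in every test and count. Groups, comparisons, tests, lists, the named-gene rule and the alternatives were set before the data were examined, apart from those said to be chosen later. The alternatives covered background, offset, scaling, filter, probe rule, spread estimate, array weights, replicate block, thresholds and leaving out each array.

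The fit was tested on simulated data with 200 of 15650 genes changed. At a log2 change of 1 it recovered 52% at day 4, 60% at day 16, 59% for the knockdown, 50% for time and 4% for the difference of the dox effects. At a log2 change of 2 it recovered 100%, 99%, 100%, 100% and 91%. False calls made up 2.56%, 9.14%, 4.79%, 4.46% and 5.94% of the calls, and 0 calls had the wrong sign. The simulated groups had equal spread. In the data the SD of the replicate difference ran from 0.25 in shLuc to 0.51 in dox-minus day 16 cells. The simulated rates therefore need not hold for the groups with the wider spread.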

Results

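Gene expression was measured on 12 Illumina bead arrays in the human embryonic stem cell line H9, in a series on LHX2, a LIM-homeodomain transcription factor of the eye field and forebrain. In the overexpression arm, cells with a doxycycline-inducible LHX2 construct were either left without the drug (dox-minus) or given it for 3 days (dox-plus), and RNA was taken at day 4 and at day 16, which is 1 and 13 days after the treatment. In the knockdown arm, cells carrying a short hairpin RNA against LHX2 (shLHX2) were set against cells with a hairpin against luciferase (shLuc) after 12 days of neural induction. Each of the 6 groups held 2 arrays, which the series describes as biological duplicates. The arrays detected between 19050 and 20489 of 47227 probes, and the number of arrays limits the precision of every value. Pearson correlations across genes, which are not independent replicates, ran from 0.976 to 0.994 within groups and from 0.901 to 0.989 between groups. The comparisons ask how dox-plus and dox-minus cells differ early and late, and what lowered LHX2 does during neural induction. A further one asks which genes change with time without the drug. The series text also names GFP as a control of the overexpression arm. The labels of these arrays name dox-minus and dox-plus LHX2 cells only, so the comparison made was dox-plus against dox-minus. An effect of doxycycline itself therefore cannot be told apart from one of LHX2. Values are normalized log2 signals, fold changes carry the standard error (SE) of the fit, and adjusted p-values come from limma with Benjamini-Hochberg adjustment over 15650 genes. For a gene detected on neither array of a group the text gives a bound, at least N-fold: the mean of the brighter group against, on each dim array, the higher of the gene's own value and the lowest detected signal of that array.

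LHX2 itself was near the detection limit at day 4, with a log2 signal of 5.05 ± 0.25 (SD, n = 2) in dox-minus and 5.75 ± 0.42 (SD, n = 2) in dox-plus cells. It was detected on 1 of 2 dox-plus arrays and on 0 of 2 dox-minus arrays, a difference of at least 1.05-fold that did not pass the test (limma adjusted p = 0.272). At day 16 LHX2 stood at 12.06 ± 0.19 (SD, n = 2) in dox-minus and 12.91 ± 0.17 (SD, n = 2) in dox-plus cells. That difference of 0.86 ± 0.27 (SE) on the log2 scale also missed the threshold (limma adjusted p = 0.0581). The miss depended on the background step. Without background correction limma's adjusted p was 0.0172, and with offset 50 it was 0.0222. With cyclic loess, median scaling and the unnormalized series values the difference missed the threshold as well. In the knockdown arm LHX2 fell from 9.75 ± 0.03 (SD, n = 2) in shLuc to 7.72 ± 0.52 (SD, n = 2) in shLHX2 cells. The log2 fold change was -2.03 ± 0.27 (SE; limma adjusted p = 0.00592). The array has 1 probe for LHX2, which starts at base 2100 of its transcript, near the 3′ end. Whether the doxycycline-driven construct carries that part of the transcript is not given in the sources used here. The probe therefore does not check the dox labels.

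PAX6, the paired-box regulator of neuroectoderm and eye, fell in shLHX2 cells by 1.57 ± 0.22 on the log2 scale (limma adjusted p = 0.0079). It was below detection in both dox groups at day 4, and its difference at day 16, 0.59 ± 0.22, did not pass the test (limma adjusted p = 0.0972). CER1, the secreted antagonist Cerberus of BMP and Nodal ligands, rose in dox-plus cells at day 4 by 1.24 ± 0.25 (limma adjusted p = 0.0301) and was at least 2.51-fold lower in shLHX2 than in shLuc cells (limma adjusted p = 0.033). At day 16 CER1 was detected on 1 of 2 dox-minus arrays and on 0 of 2 dox-plus arrays, and its difference did not pass the test (limma adjusted p = 0.379). Leaving out 1 array at a time ended the knockdown calls of LHX2, PAX6 and CER1. Limma's adjusted p was 0.106 for LHX2 without shLuc replicate 1, and 0.145 for PAX6 and 0.351 for CER1 without shLuc replicate 2. At day 4 that of CER1 was 0.202 without dox-minus replicate 1. For LHX2 the adjusted p was also 0.104 without shLuc replicate 2 and 0.071 without shLHX2 replicate 1, with log2 fold changes from -2.40 to -1.66.

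**Figure D1:**
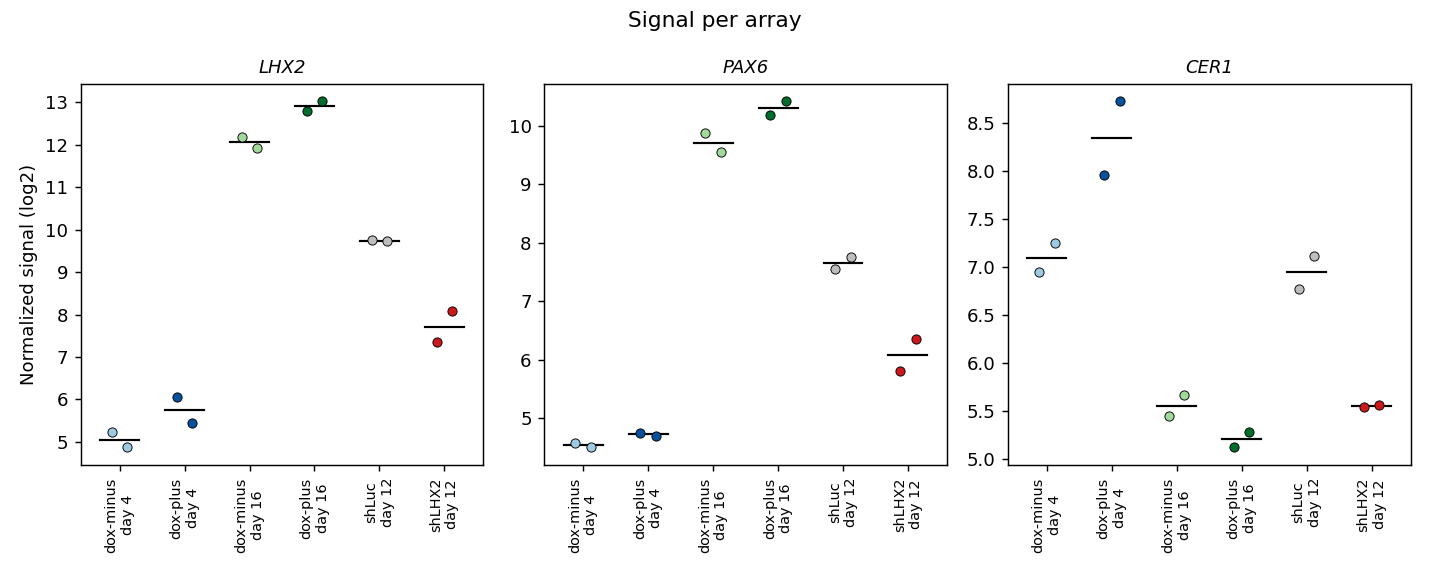
Normalized log2 signal (y axis) of LHX2, PAX6 and CER1 on each of the 12 arrays, by group (x axis); points are arrays and bars are means of 2 arrays. LHX2 lay at 7.72 in shLHX2 against 9.75 in shLuc cells and at 12.06 and 12.91 in the day 16 groups, and CER1 at 8.34 in dox-plus against 7.10 in dox-minus cells at day 4.

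At day 4, 1 day after the drug was removed, NODAL, a TGF-beta family ligand, was at least 2.41-fold higher in dox-plus cells, and its feedback antagonists LEFTY1 and LEFTY2 rose by 2.05 ± 0.40 and 1.82 ± 0.38 (log2 ± SE, n = 2 against 2). The neuronal transcription factor ISL1 fell by 1.70 ± 0.21, TBX1, a T-box gene of pharyngeal mesoderm, fell by 1.72 ± 0.35, and NKX3-2, a homeobox gene of skeletal mesoderm, was at least 3.63-fold lower. The largest rises were those of NNAT, an imprinted gene of the developing brain, and SLC35E3, a solute carrier family member, at 4.21 ± 0.27 and 3.37 ± 0.24. The neuropeptide genes CALCB and NPY were at least 3.56-fold and at least 2.87-fold higher. The deepest falls were those of TMSB15A, a beta-thymosin, at -4.42 ± 0.25, NLRP2 at -3.19 ± 0.27 and IAH1 at -3.09 ± 0.22, while the TRIM-family gene TRIM4 and the zinc finger gene ZNF558 were at least 3.01-fold and at least 2.64-fold lower. VWF, at 1.81 ± 0.28, and CLOCK, at 1.79 ± 0.31, also rose. Probes annotated to CHCHD2P9 and CHCHD2P2 fell by 2.71 and 2.40, and as copies of CHCHD2 they cannot be assigned with certainty.

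By gene list, 3 of 9 tested Nodal and activin targets rose at day 4 (NODAL, LEFTY1 and LEFTY2; 3 adjusted over the list alone), while the list as a whole did not pass camera, limma's competitive set test (adjusted p = 0.0905). Of 13 secreted antagonists of BMP, WNT and Nodal, 2 rose, CER1 and SFRP2 (2 adjusted over the list alone). In the list of 16 mesendoderm and mesoderm genes 2 fell, TBX1 and the cardiac actin ACTC1, with 2 adjusted over the list alone. Single members fell or rose in other lists: the surface ectoderm gene DLX5 by 1.23 ± 0.27 and the smooth muscle actin ACTA2 by 0.99 ± 0.18 downward, and the FGF feedback gene IL17RD by 1.07 ± 0.24 upward. The neuron list of 20 genes had a median log2 fold change of -0.25 (-0.19 with genes below detection set at their bound) and was the 1 list of 22 that camera called (adjusted p = 0.00578; adjusted p = 0.421 with an estimated correlation). ISL1 was its 1 called member, and 3 were lower when adjusted over the list alone. No member of the pluripotency, neural progenitor, forebrain, Notch or proliferation lists passed limma's threshold at day 4. The largest changes among them were 1.07 ± 0.34 for GDF3, 1.01 ± 0.37 for POU3F1, 1.26 ± 0.41 for OTX1, 0.43 ± 0.28 for DLL1 and 0.78 ± 0.24 for RRM2.

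In total, limma called 302 of 15650 genes at day 4 at a Benjamini-Hochberg adjusted p under 0.05, 209 higher and 93 lower in dox-plus cells. That number became 30 and 28 without dox-minus replicate 1 and 2, and 93 and 142 without dox-plus replicate 1 and 2. Without dox-minus replicate 2 limma's adjusted p was 0.101 for NPY, 0.2 for LEFTY1, 0.244 for LEFTY2, 0.14 for VWF, 0.172 for CLOCK, 0.191 for NODAL, 0.191 for TBX1, 0.143 for ACTC1, 0.245 for DLX5 and 0.297 for IL17RD. Without dox-minus replicate 1 it was 0.0534 for ISL1, 0.202 for SFRP2 and 0.148 for ACTA2. No such fit ended the calls of NNAT, SLC35E3, CALCB, TMSB15A, NLRP2, IAH1, TRIM4, ZNF558 and NKX3-2. The share of higher genes, 69.2% here, was 87.1% with median scaling and 93.6% on the unnormalized series values, where the median of all genes lay 0.15 and 0.23 above 0 on the log2 scale.

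At day 16, 13 days after the drug was removed, 11 of 22 neural progenitor genes and 9 of 19 forebrain and eye field genes were higher in dox-plus than in dox-minus cells, with 1 lower in each list. Camera called both lists, but not with an estimated correlation (limma adjusted p = 0.0551 for each). FABP7, the fatty acid binding protein of radial glia, rose by 3.80 ± 0.48 (log2 ± SE, n = 2 against 2), HES5, a Notch effector of neural progenitors, by 2.96 ± 0.22, and SP8, a zinc finger gene of the anterior forebrain, by 3.25 ± 0.20. FGF8, the ligand of the anterior neural ridge, rose by 3.48 ± 0.25. Among lower genes, HOXB8 was at least 21.5-fold and HOXB5 at least 30.5-fold lower, the collagens COL6A3 and COL3A1 fell by 4.28 ± 0.20 and 4.00 ± 0.25, and APLNR, the apelin receptor of early mesoderm, was at least 15.4-fold lower.

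The remaining leading genes at day 16 were of several kinds. H19, an imprinted non-coding RNA, was at least 50.9-fold higher in dox-plus cells, whereas IGF2, its neighbour at the same imprinted locus, was at least 36.1-fold lower. The read-through gene INS-IGF2, whose transcripts overlap IGF2, was at least 22.4-fold lower. TMSB15A rose by 4.78 ± 0.25, SLITRK1, a synaptic adhesion gene, by 3.73 ± 0.20 and IAH1 by 3.46 ± 0.22, and TRIM4 and ZNF558 were at least 6.28-fold and at least 6.73-fold higher. CRHBP, which encodes the corticotropin-releasing hormone binding protein, was at least 37.0-fold lower, EGFLAM at least 45.2-fold lower and SRPX2 at least 15.1-fold lower, while PITX1, a hindlimb homeobox gene, fell by 5.03 ± 0.29. Each of these 16 leading genes had a limma adjusted p below that of FABP7, which was 0.000318, or equal to it.

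Of 22 tested neural progenitor genes 11 rose and 1 fell, and 13 and 3 did when adjusted over the list alone. LMO3 rose by 2.48 ± 0.29 and DACH1 by 2.17 ± 0.24, and camera called the list upward (adjusted p = 3.61e-05; adjusted p = 0.0551 with an estimated correlation). In the forebrain and eye field list 9 of 19 genes rose and 1 fell, or 10 and 2 adjusted over the list alone. DMRT3 was at least 3.22-fold higher and EMX1 rose by 1.67 ± 0.36 (camera for the list, adjusted p = 6.39e-05; adjusted p = 0.0551 with an estimated correlation). Of 13 Notch pathway genes 7 rose and 0 fell, or 8 and 0 adjusted over the list alone. The ligand DLL1 rose by 2.31 ± 0.28 and the fringe enzyme MFNG by 1.94 ± 0.21 (camera for the list, adjusted p = 8.16e-06; adjusted p = 0.0886 with an estimated correlation). In the FGF feedback list 4 of 11 genes rose and 1 fell, or 4 and 2 adjusted over the list alone. SPRY1 and ETV5 rose by 1.37 ± 0.22 and 1.34 ± 0.21, and SPRY4 fell by 0.81 ± 0.24 (camera for the list, adjusted p = 0.0178; adjusted p = 0.0886 with an estimated correlation). In the neuron list 6 of 20 genes rose and 3 fell, or 8 and 4 adjusted over the list alone. The dendritic protein gene MAP2 rose by 2.60 ± 0.17, NEUROG2 by 2.40 ± 0.25 and DCX by 1.24 ± 0.18, while limma's camera did not call the list (adjusted p = 0.0696).

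The mesenchyme and fibroblast list fell at day 16 in 12 of 14 genes, and in 12 adjusted over the list alone. Its median log2 fold change was -1.72, also with genes below detection set at their bound (camera adjusted p = 1.18e-12; adjusted p = 0.0433 with an estimated correlation). DCN, the proteoglycan decorin, fell by 3.05 ± 0.24 and COL5A1 fell by 2.69 ± 0.26. Of 16 mesendoderm and mesoderm genes 10 fell and 1 rose, or 12 and 1 adjusted over the list alone (camera adjusted p = 6.93e-10; adjusted p = 0.00922 with an estimated correlation). PDGFRA fell by 3.98 ± 0.23, HAND1 fell by 2.94 ± 0.37 and FOXF1 was at least 4.80-fold lower. In the midbrain, hindbrain and spinal list 4 of 6 genes fell and 1 rose, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.00405; adjusted p = 0.0886 with an estimated correlation). HOXB2 fell by 2.83 ± 0.23, HOXB3 and HOXB4 were at least 1.94-fold and at least 1.41-fold lower, and the midbrain-hindbrain gene GBX2 rose by 1.15 ± 0.28. Endoderm genes rose in 2 of 10 and fell in 4 (2 and 6 adjusted over the list alone), with APOA1 at least 13.3-fold lower. Neural crest and placode genes rose in 2 of 15 and fell in 4 (3 and 5 adjusted over the list alone), with MSX1 at -2.52 ± 0.34. Surface ectoderm and trophoblast genes also rose in 2 of 15 and fell in 4 (3 and 5 adjusted over the list alone), with KRT17 at -2.21 ± 0.32. Limma's camera called none of these last lists (adjusted p = 0.0608, 0.266 and 0.162).

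BMP targets fell in 5 of 12 genes, and 1 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.203 with an estimated correlation). BAMBI fell by 2.56 ± 0.24 and BMP4 fell by 2.11 ± 0.20, and the BMP regulator BMPER was at least 8.04-fold lower. Nodal and activin targets fell in 3 of 9, and in 3 adjusted over the list alone, with WNT3 at -1.19 ± 0.24 (camera adjusted p = 0.0178; adjusted p = 0.192 with an estimated correlation). Their median log2 fold change was -0.57, or 0 with genes below detection at their bound. WNT targets fell in 2 of 12, LEF1 at -1.68 ± 0.29 and TNFRSF19 at -1.29 ± 0.19, and in 2 adjusted over the list alone (camera adjusted p = 0.0321; adjusted p = 0.1 with an estimated correlation). The secreted antagonists rose in 2 of 13 genes and fell in 3 (3 and 4 adjusted over the list alone), with FRZB at 2.25 ± 0.22 (limma's camera, adjusted p = 0.877).

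The stress kinase, amino acid and p53 response list fell in 11 of 17 genes at day 16, and in 12 adjusted over the list alone, with CHAC1 at -1.56 ± 0.26 and TRIB3 at -1.46 ± 0.19. Camera called it downward (adjusted p = 1.76e-06; adjusted p = 0.0157 with an estimated correlation). Of 9 interferon response genes 6 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00122; adjusted p = 0.0742 with an estimated correlation). MX1 fell by 3.45 ± 0.21 and IFIT1 rose by 2.01 ± 0.34. Immediate early genes fell in 7 of 12 and rose in 1, BTG2, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.000219; adjusted p = 0.0551 with an estimated correlation). Hypoxia genes fell in 4 of 13, and in 5 adjusted over the list alone, with NDRG1 at -1.75 ± 0.28 (camera adjusted p = 0.0178; adjusted p = 0.192 with an estimated correlation). Among pluripotency genes 4 of 19 fell, and 3 rose and 4 fell adjusted over the list alone. NANOG fell by 1.62 ± 0.24 and POU5F1 fell by 1.25 ± 0.22, without a call for the list (limma's camera, adjusted p = 0.914). Proliferation genes rose in 3 of 20, TOP2A, KIF11 and CCNB1, and in 3 adjusted over the list alone (limma's camera, adjusted p = 0.0591). The cortical hem and choroid plexus list rose in 2 of 8 genes and fell in 2, also when adjusted over the list alone (limma's camera, adjusted p = 0.797). The retinal pigment epithelium list had 2 tested members, too few for a set test, of which PMEL rose by 0.64 ± 0.19. Of the 14 lists camera called at day 16, 3 held with an estimated correlation: mesendoderm, mesenchyme and the stress response.

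Of 15650 genes, limma called 2148 at day 16 at a Benjamini-Hochberg adjusted p under 0.05, 952 higher and 1196 lower in dox-plus cells. The number fell when dox-minus replicate 1 or either dox-plus array was left out, and rose when dox-minus replicate 2 was left out. Pearson correlations with the dox-plus arrays across genes were 0.963 and 0.965 for dox-minus replicate 2, and 0.934 and 0.954 for dox-minus replicate 1. In every such fit, dox-minus replicate 2 included, 77 of 99 named genes kept an adjusted p under 0.05. Limma's adjusted p rose to 0.0877 for WNT3, 0.139 for GBX2, 0.198 for SPRY4, 0.128 for TOP2A and 0.241 for CCNB1 without dox-plus replicate 1. It rose to 0.0825 for EMX1, 0.233 for PMEL and 0.0967 for KIF11 without dox-plus replicate 2, and to 0.109 for BTG2 without dox-minus replicate 1.

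**Figure D2:**
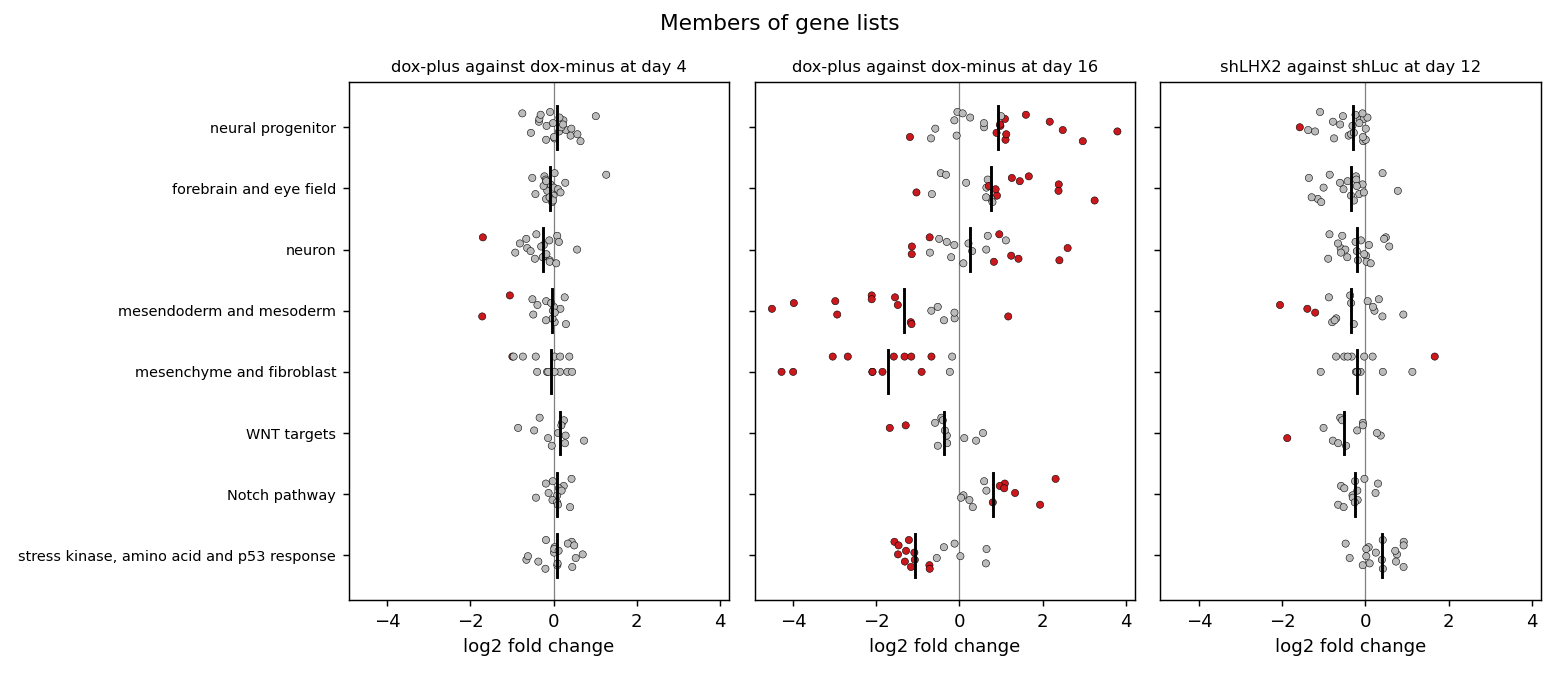
Log2 fold changes (x axis) of the members of 8 gene lists (y axis) in the day 4, day 16 and knockdown comparisons; each point is a gene, red where its limma adjusted p was under 0.05 over all genes and grey otherwise, and bars are list medians. The mesenchyme list had a median of -1.72 at day 16, against 0.93 (0.74 with genes below detection at their bound) for the neural progenitor list.

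The dox effect differed between the days for many genes, by limma's test of the difference itself (day 16 effect minus day 4 effect). TMSB15A, H19, ZNF558, IAH1, TRIM4 and NLRP2 had the largest positive differences, 9.21 ± 0.35, 8.93 ± 0.37, 6.57 ± 0.34, 6.55 ± 0.31, 6.27 ± 0.27 and 4.84 ± 0.39 (log2 ± SE). Each was lower in dox-plus cells at day 4 and higher at day 16. NNAT and SLC35E3 went the other way, with differences of -5.94 ± 0.38 and -5.20 ± 0.34, and HOXB8, EGFLAM, CRHBP and HOXB5 had differences of -5.84, -5.62, -5.59 and -5.37 that came from the day 16 arrays. Fitted differences of genes below detection in a group depend on the background. TRIM4 had log2 signals of 7.23 ± 0.30 and 8.21 ± 0.16 (SD, n = 2) in dox-minus day 4 and dox-plus day 16 cells. In dox-plus day 4 and dox-minus day 16 cells it was below detection, with signals of 4.56 ± 0.06 and 4.60 ± 0.04. In all, 14 genes, H19, IAH1, NLRP2, OLIG2, RNF212, TMSB15A, TRIM4, ZNF558, EGFL6, NPY, PSMD5, QPCT, SLC35E3 and ZNF717, separated the 8 dox arrays across the labels in this way by a gap of at least 1 on the log2 scale, whereas 0 genes did so by the dox label and 395 by the day. The criterion was set after the values were seen and gave 0 crossed genes on average in 20 simulations of noise alone. Those simulations held no effect of day or drug. They do not show how many genes would cross through separate drug effects at the 2 days.

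Among lists, mesendoderm (median difference -1.14; camera adjusted p = 4.95e-07; adjusted p = 0.0238 with an estimated correlation) and the stress response list (median difference -0.94; camera adjusted p = 1.79e-05; adjusted p = 0.025 with an estimated correlation) had a lower dox effect at day 16 than at day 4. Camera called 14 lists for the difference, 2 of them with an estimated correlation. Limma called 1229 of 15650 genes for the difference, 496 positive and 733 negative. That number was 659 and 677 without dox-minus day 4 replicate 1 and 2, 805 and 2136 without dox-minus day 16 replicate 1 and 2, and 584 and 776 without dox-plus day 16 replicate 1 and 2. The share of positive differences was 40.4%, against 28.3% with median scaling and 17.0% on the unnormalized series values, which moved the median of all genes to -0.15 and -0.23.

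**Figure D3:**
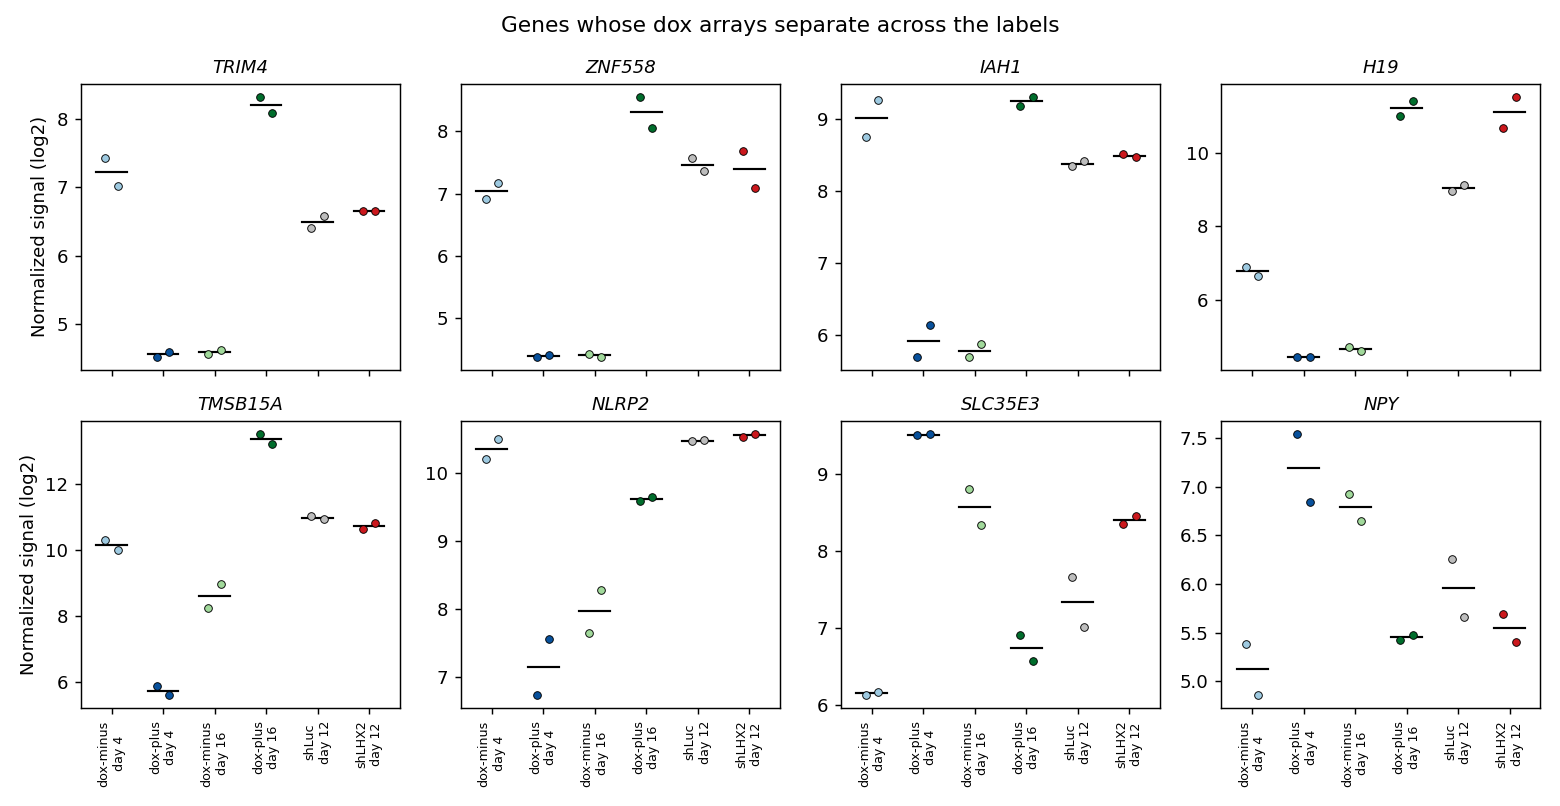
Normalized log2 signal (y axis) on each array, by group (x axis), of 8 of the 14 genes whose dox arrays separate across the labels; points are arrays and bars are means of 2 arrays. TRIM4 lay at 7.23 and 8.21 in dox-minus day 4 and dox-plus day 16 cells against 4.56 and 4.60 in the other dox groups, and at 6.50 and 6.65 in shLuc and shLHX2 cells.

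In the knockdown arm, several secreted antagonists were lower in shLHX2 than in shLuc cells at day 12. DKK1, a WNT antagonist, fell by 1.78 ± 0.24 (log2 ± SE, n = 2 against 2), SFRP2 and FRZB, secreted frizzled-related WNT antagonists, by 1.28 ± 0.20 and 1.22 ± 0.22, and CER1 was at least 2.51-fold lower. EOMES, a T-box gene of mesendoderm, fell by 2.05 ± 0.27, TEK, the endothelial receptor TIE2, by 2.12 ± 0.19, and DLK1, an imprinted non-canonical Notch ligand, by 1.88 ± 0.24. APOA1, CST1 and SP5, a WNT target, were at least 3.65-fold, at least 2.52-fold and at least 2.89-fold lower, and SORBS2 fell by 1.86 ± 0.34. The largest rises were those of the lysosomal protease CTSF at 2.56 ± 0.22, the immune checkpoint ligand VTCN1 at 2.21 ± 0.27, LRRC61 at 2.13 ± 0.36, H19 at 2.07 ± 0.26 and ECHDC3 at 2.02 ± 0.20. ZNF667-AS1, IZUMO2 and CIDEB were at least 2.78-fold, at least 2.85-fold and at least 1.94-fold higher.

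The secreted antagonist list had 4 of 13 members lower, 5 adjusted over the list alone, and a median log2 fold change of -0.66, also with genes below detection at their bound (camera adjusted p = 6.86e-08; adjusted p = 0.0168 with an estimated correlation). Neural progenitor genes had a median of -0.29 (-0.19 at the bounds), with PAX6 as the 1 called member of 22 and 4 lower adjusted over the list alone. Camera called the list downward (adjusted p = 5.63e-06; adjusted p = 0.0322 with an estimated correlation). Of 19 forebrain and eye field genes 0 passed limma's threshold and 4 were lower adjusted over the list alone, with SIX3 at -1.36 ± 0.36. Camera called this list downward too (adjusted p = 9.7e-05; adjusted p = 0.0446 with an estimated correlation). Mesendoderm genes fell in 3 of 16, EOMES, APLNR and TBXT, and in 4 adjusted over the list alone (camera adjusted p = 0.000151; adjusted p = 0.0322 with an estimated correlation). Endoderm genes fell in 1 of 10, APOA1, and in 5 adjusted over the list alone (camera adjusted p = 0.000119; adjusted p = 0.0377 with an estimated correlation). WNT targets fell in 1 of 12, SP5, and in 4 adjusted over the list alone (camera adjusted p = 0.000444; adjusted p = 0.0322 with an estimated correlation). The stress response list was called upward with 0 of 17 members past limma's threshold and 5 higher adjusted over the list alone (camera adjusted p = 0.0004; adjusted p = 0.0322 with an estimated correlation). These 7 of 15 calls held with an estimated correlation.

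FGF feedback genes fell in 2 of 11, DUSP6 by 1.28 ± 0.21 and FGF8 at least 1.61-fold lower (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00949; adjusted p = 0.0809 with an estimated correlation). The surface ectoderm and trophoblast list had 0 of 15 members called over all genes and 7 higher adjusted over the list alone (camera adjusted p = 0.000151; adjusted p = 0.162 with an estimated correlation). Camera also called the cortical hem, neuron, Nodal and Notch lists downward (adjusted p = 0.0838, 0.162, 0.198 and 0.283 with an estimated correlation). It called the BMP target and interferon lists upward (adjusted p = 0.403 and 0.106 with an estimated correlation). The BMP target ID1 rose by 1.22 ± 0.24, the interferon-induced gene IFI6 by 1.17 ± 0.23, and HOXB2 by 1.51 ± 0.23. In the mesenchyme list DCN rose by 1.67 ± 0.24, and limma's camera did not call the list (median -0.19, or -0.15 at the bounds; adjusted p = 0.364).

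Limma called 85 of 15650 genes in the knockdown comparison at a Benjamini-Hochberg adjusted p under 0.05, 39 higher and 46 lower in shLHX2 cells. The number was 24 and 25 without shLHX2 replicate 1 and 2, and 10 and 12 without shLuc replicate 1 and 2. Of the 30 named genes called, CTSF, ZNF667-AS1, IZUMO2, CIDEB, ECHDC3, CST1 and TEK kept an adjusted p under 0.05 in each of these fits. Without shLuc replicate 1 limma's adjusted p was 0.106 for H19, EOMES, DLK1 and APLNR, 0.111 for DKK1, 0.236 for SFRP2, 0.403 for FRZB, 0.173 for FGF8, 0.28 for DUSP6, 0.29 for LRRC61, 0.15 for TBXT and 0.497 for ID1. Without shLuc replicate 2 it was 0.0806 for VTCN1, 0.145 for APOA1, 0.11 for SP5, 0.325 for SORBS2, 0.22 for HOXB2 and 0.146 for DCN, and without shLHX2 replicate 2 it was 0.395 for IFI6. The share of higher genes, 45.9%, was 28.9% with median scaling and 16.5% on the unnormalized series values, where the median of all genes lay at -0.13 and -0.18 on the log2 scale.

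Between day 4 and day 16 without the drug, genes of the eye field and of mesenchyme were among the largest rises, and 15 of 19 pluripotency genes fell. LHX2 was at least 83.5-fold, PAX6 at least 16.4-fold, and the eye field genes RAX and SIX6 at least 33.6-fold and at least 9.03-fold higher at day 16. The matrix genes COL3A1 and LUM were at least 92.5-fold and at least 39.9-fold higher, the homeodomain-only gene HOPX at least 49.1-fold, and DLK1 rose from 8.61 ± 0.10 to 14.61 ± 0.11 (log2 ± SD, n = 2 each). EGFLAM was at least 40.4-fold higher and PITX1 rose by 5.66 ± 0.29 (log2 ± SE). NANOG and POU5F1 fell by 2.19 ± 0.24 and 1.79 ± 0.22, and AFP, the alpha-fetoprotein of endoderm, fell by 3.45 ± 0.24. SFTA1P, AADACL3, ABHD12B, GARIN1B, IAH1 and GLIPR1L1 had log2 fold changes of -3.96, -3.50, -3.48, -3.28, -3.22 and -3.13, and DNER was at least 4.27-fold lower.

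Pluripotency genes fell in 15 of 19 (16 adjusted over the list alone; camera adjusted p = 3.36e-10; adjusted p = 0.0136 with an estimated correlation). Neural progenitor genes rose in 13 of 22 and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 4.92e-10; adjusted p = 0.0136 with an estimated correlation), with HES5 at 4.98 ± 0.22. Forebrain and eye field genes rose in 12 of 19 and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 6.31e-10; adjusted p = 0.0136 with an estimated correlation). Of 16 mesendoderm genes 10 rose and 2 fell, or 11 and 2 adjusted over the list alone, with HAND1 at 4.97 ± 0.37 (camera adjusted p = 9.35e-09; adjusted p = 0.0136 with an estimated correlation). Of 14 mesenchyme genes 10 rose and 2 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 4.25e-07; adjusted p = 0.0523 with an estimated correlation). Of 15 surface ectoderm and trophoblast genes 10 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 3.65e-06; adjusted p = 0.0779 with an estimated correlation). Of the neural crest genes, SNAI2 was at least 19.7-fold higher and MSX1 rose by 4.02 ± 0.34, and BMP targets rose in 8 of 12 (8 adjusted over the list alone; camera adjusted p = 3.47e-08; adjusted p = 0.0642 with an estimated correlation). Camera called 16 lists, 9 of them with an estimated correlation. Limma called 2824 genes, 1518 higher and 1306 lower at day 16, and 1626 and 1599 without dox-minus day 4 replicate 1 and 2. The share of higher genes was 53.8%, against 70.4% on the unnormalized series values. Some of the named genes lost their call in a fit that left out 1 array.

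Calls were then compared between experiments that share no array. Of the genes called in both dox comparisons, 28 changed in the same direction at day 4 and day 16, against 19.8 for independent lists. Among them were BIK, ACTC1, TEK, CYP4X1, EPHA4 and HPGD. Neither direction of this overlap passed Fisher's exact test (adjusted p = 0.353 for higher and 0.0981 for lower genes). In opposite directions there were 60 against 21.6, among them TMSB15A, H19, IAH1, ZNF558, TRIM4 and NNAT. Genes lower at day 4 and higher at day 16 numbered 29 against 5.66 (Fisher's exact test, adjusted p = 7.01e-13 over 16 tests). Between dox-plus at day 16 and the knockdown, 24 genes changed in opposite directions against 5.78 for independent lists, among them FGF8, DCN, HOXB2, FRZB, PTGS1 and ECHDC3. In the same direction there were 13 against 5.89, among them H19, CST1, APOA1, APLNR, TEK and NTS. Between dox-plus at day 4 and the knockdown, EPHA4, CER1, SEZ6, SFRP2, PDIA3P1 and H19 changed in opposite directions, 6 genes against 0.846 for independent lists. In the same direction there were 9 against 0.794, among them CALCB, PSMD5, TEK, COX7A1, ECHDC3 and GRM3. Genes that changed with knockdown against the direction of time numbered 35 against 7.72, with LHX2, DLK1, PAX6, CST1, DKK1 and APLNR among them. With time went 14 against 7.62, among them VTCN1, DCN, HOXB2, ZNF667-AS1, PSMD5 and IFI6. Lower after knockdown and higher at day 16 were 27 genes (4.46 for independent lists; Fisher's exact test, adjusted p = 3.78e-15).

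All comparisons share 1 estimate of the spread per gene, which can raise any overlap in either direction, and genes are not independent. The 28 genes with the same direction at both days became 1 and 0 without dox-minus day 4 replicate 1 and 2, 8 and 12 without dox-plus day 4 replicate 1 and 2, and 9 and 10 without dox-plus day 16 replicate 1 and 2. The 24 genes with opposite directions at day 16 and after knockdown became 11 and 11 without dox-plus day 16 replicate 1 and 2, 6 and 5 without shLHX2 replicate 1 and 2, and 3 and 3 without shLuc replicate 1 and 2. The 6 such genes of day 4 became 1 without either dox-minus array or either shLHX2 array, 3 without dox-plus replicate 1, 9 without dox-plus replicate 2 and 0 without either shLuc array. The 35 genes of knockdown against time became 23 and 20 without dox-minus day 4 replicate 1 and 2, 4 and 11 without shLHX2 replicate 1 and 2, and 1 and 3 without shLuc replicate 1 and 2.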

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

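The tests of the named genes and lists in this part were planned, whereas the count of genes that separate across the labels, the simulations behind it and the tests that weigh it were chosen only after the result was seen. The results here stand out because the dox effect differed between the days, by limma's interaction test with a Benjamini-Hochberg adjusted p under 0.05. In all 1229 genes passed it. Some of the named genes lost this call in a fit that left out an array, which leaves a lone array in a group. Values are log2 differences, day 16 effect minus day 4 effect, and a positive value means a higher dox effect at day 16. A fitted difference of a gene below detection in a group depends on the background and is no bound.

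By list, counting genes that limma called, 8 of 22 neural progenitor genes had a higher dox effect at day 16 and 1, PLAGL1, a lower effect. Among the higher were FABP7 3.66, DACH1 2.53, HES5 2.32 and LMO3 2.18. In the forebrain and eye field list 5 of 19 were higher, among them SP8 3.26, DMRT3 2.46 and EMX1 1.89, and 1 was lower. In the neuron list 5 of 20 were higher, among them MAP2 3.24, NEUROG2 2.50, MYT1 1.87 and DCX 1.46, and 0 were lower. Of 13 Notch genes 4 were higher (DLL1 1.88, MFNG 1.83, NRARP 1.46 and HES4 1.28) and 0 lower, and of 11 FGF feedback genes 3 were higher (FGF8 3.25, ETV5 1.76 and SPRY1 1.35) and 0 lower. The other genes of these lists were not called.

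Of 16 mesendoderm and mesoderm genes 8 had a lower dox effect at day 16, among them APLNR -4.67, PDGFRA -3.92, FOXF1 -2.81, HAND1 -2.45 and ACTC1 -1.06, and 1 a higher effect, TBX1 2.89. Of 14 mesenchyme genes 7 were lower, among them COL3A1 -4.44, COL6A3 -4.12, DCN -3.07 and COL5A1 -2.25, and 0 higher. Of 6 midbrain, hindbrain and spinal genes 3 were lower (HOXB2 -2.81, HOXB3 -1.66 and HOXB4 -1.04) and 0 higher. Of 10 endoderm genes 3 were lower (APOA1 -3.73, FOXA2 -2.12 and GATA4 -1.61) and 1 higher (FOXA1 1.35). Of 15 surface ectoderm genes 3 were lower (GATA2 -2.69, KRT17 -2.40 and KRT7 -1.64) and 1 higher (DLX5 3.07). Of 15 neural crest genes 3 were lower (MSX1 -2.92, SNAI2 -2.34 and EDNRB -1.79) and 2 higher, with SOX9 at 1.27. Of 19 pluripotency genes 2 were lower (NANOG -1.78 and PRDM14 -1.64) and 0 higher. Of 8 cortical hem and choroid plexus genes 1 was lower (BMP6 -2.03) and 2 higher (CLIC6 1.80 and RSPO1 0.98).

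Of 12 BMP targets 5 had a lower dox effect at day 16 (BMPER -3.58, BAMBI -2.28, SMAD6 -1.78, SMAD7 -1.68 and BMP4 -1.36) and 0 a higher effect. Of 9 Nodal and activin targets 5 were lower, among them LEFTY1 -2.62, LEFTY2 -2.42, NODAL -2.10 and CFC1 -1.66, and 0 higher. Of 12 WNT targets 1 was lower (TNFRSF19 -1.48) and 0 higher. Of 13 secreted antagonists 2 were lower (DKK1 -1.67 and CER1 -1.60) and 2 higher (FRZB 2.07 and SOSTDC1 1.14). Of 17 stress response genes 7 were lower, among them DDIT3 -2.18, CHAC1 -1.998, TRIB3 -1.96 and DDIT4 -1.61, and 0 higher. Of 9 interferon response genes 3 were lower (MX1 -3.38, IRF9 -1.56 and IFITM1 -1.51) and 1 higher (IFIT1 2.08). Of 12 immediate early genes 2 were lower (JUNB -1.88 and JUN -1.03) and 1 higher (BTG2 2.67). Of 13 hypoxia genes 1 was lower (NDRG1 -1.73) and 0 higher.

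Outside the lists, lower dox effects at day 16 were those of HOXB8 -5.84, HOXB5 -5.37, NNAT -5.94, EGFLAM -5.62, CRHBP -5.59, SLC35E3 -5.20, INS-IGF2 -5.13, IGF2 -4.89, SRPX2 -4.85, PITX1 -4.40, CALCB -4.03, NPY -3.40, VWF -1.94 and CLOCK -1.84. Higher effects were those of TMSB15A 9.21, H19 8.93, ZNF558 6.57, IAH1 6.55, TRIM4 6.27, NLRP2 4.84, SLITRK1 3.85, CHCHD2P9 3.23, CHCHD2P2 2.85 and NKX3-2 2.72.

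Camera called 14 lists for this difference. Median differences were positive for neural progenitor (0.68), forebrain and eye field (0.87), neuron (0.73), Notch pathway (0.72) and FGF feedback (0.36). They were negative for midbrain, hindbrain and spinal (-0.56), mesendoderm and mesoderm (-1.14), endoderm (-0.89), mesenchyme and fibroblast (-1.71), BMP targets (-0.32), Nodal and activin targets (-1.66), interferon response (-0.80), stress kinase, amino acid and p53 response (-0.94) and immediate early (-0.65). With an estimated correlation camera called 2 of them, mesendoderm and the stress response. Medians of the difference were not taken at the bounds. For the day 16 effect alone, the endoderm median of -0.67 became -0.06 with genes below detection at their bound. That of Nodal and activin targets went from -0.57 to 0, that of mesendoderm from -1.33 to -0.92 and that of neuron from 0.26 to 0.05. The day 16 medians of mesenchyme, -1.72, and the stress response, -1.07, stayed.

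Of 15650 genes, 14 separated the 8 dox arrays across the labels, high in dox-minus day 4 and dox-plus day 16 or the reverse, by at least 1 on the log2 scale. Without a required gap 482 did so, while 651 separated by the dox label and 3992 by the day. Arrays that are all alike would give 447, but with so many genes separating by the day that number is no fitting reference. Normalization as the cause is argued against for 6 of the 14 genes, which kept direction and gap on the raw signals. The other 8, H19 and TMSB15A among them, separated across the labels on the raw signals only without the gap. Genes picked for a gap after normalization were likely to do so. Whether normalization made the gap of those 8 therefore stays open. Array brightness itself separated across the labels. The raw array medians were 82.3 and 79.1 in dox-minus day 4 and 83.4 and 84.7 in dox-plus day 16 arrays. They were higher in dox-plus day 4 arrays, at 89.2 and 88, and in dox-minus day 16 arrays, at 85.8 on both. Brightness moves the genes of an array together, whereas of the 6 genes that kept the gap 4 were high on the dimmer arrays and 2 on the brighter. As the whole cause for those 6 genes it is argued against, and a part in the pattern stays open. Dox labels exchanged at day 4 or at day 16 stay open. LHX2 does not decide, since its probe may not report the construct. In dox-plus cells LHX2 was at least 1.05-fold higher at day 4 (limma adjusted p = 0.272) and 0.86 higher on the log2 scale at day 16 (limma adjusted p = 0.0581). The day 16 difference passed the threshold without background correction (limma adjusted p = 0.0172) and with offset 50 (limma adjusted p = 0.0222). With cyclic loess, median scaling and the series values it did not pass. In the knockdown arm, on arrays without the drug, shLuc cells lay nearer to the dox-minus day 4 and dox-plus day 16 state for 14 of the 14 genes and shLHX2 cells for 10. This goes with an exchange at day 16, but does not tell it from a second cell population. EGFL6, OLIG2, PSMD5 and SLC35E3 changed side in shLHX2 cells, and of these only PSMD5 was called after knockdown. Some margins were narrow: EGFL6 lay at 5.95 in shLuc and 6.07 in shLHX2 cells. Other values run only in part as the labels say, if raised and lowered LHX2 act in opposite directions. Fold changes after knockdown correlated negatively across genes, which are not independent, with those of dox at day 16 (Pearson r = -0.207) and at day 4 (r = -0.145). Of the genes called in both, 24 went in opposite directions and 13 in the same at day 16, and 6 and 9 at day 4. Between dox at day 4 and dox at day 16, 60 shared calls were opposite and 28 the same (Pearson r = -0.027 across genes). By camera the neural progenitor and forebrain lists went up at day 16, though not with an estimated correlation, and down after knockdown, while mesendoderm went down in both. An exchange would turn the signs of dox at its day. Since these values point both ways and the arms are separate cultures, neither exchange nor a second cell population is decided.

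A response of these 14 genes to LHX2 that turns between the days is open as well. The knockdown cannot exclude it, since a response limited to raised LHX2 would leave genes uncalled there. Of the 14 genes 2, H19 and PSMD5, were called after knockdown, with log2 fold changes of 2.07 and 1.53. Both rose, although H19 was high in dox-minus day 4 and dox-plus day 16 cells and PSMD5 in the other dox groups. A second cell population was not tested.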

How the results depend on the processing

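The alternatives were planned, except the crossed pairing at day 16 and the exchanged labels, which were chosen only after the result was seen. The cause of a moved result was not tested. A slide or scan batch could not be run, since the files give no slide.

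The log2 difference of LHX2 at day 16, 0.86, was 0.85 without background correction (limma adjusted p = 0.0172) and 0.85 with offset 50 (limma adjusted p = 0.0222). Median scaling gave 11 genes in opposite directions at day 4 and after knockdown. The series values gave 629 calls at day 4, 1406 at day 16 and 12 such shared genes. With probes detected on all 12 arrays, 1388 genes were called at day 16, 21 after knockdown, 1770 for time and 700 for the difference. The opposite-direction overlaps were then 6 for day 16 with knockdown, 2 for day 4 with knockdown and 9 for knockdown with time.

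With only the arrays of a comparison in the fit, 61 genes were called at day 4, 1067 at day 16 and 694 for the difference, with overlaps of 2 between the days in the same direction and 3 for day 4 with knockdown. Array weights, which were equal within each group, gave 180 calls at day 4 and 418 after knockdown, with overlaps of 14 between the days, 95 for day 16 with knockdown, 15 for day 4 with knockdown and 122 for knockdown with time. A replicate block gave 47 calls at day 4 and 26 after knockdown, with overlaps of 2, 6, 2 and 12 in that order. A crossed pairing at day 16 gave 3747 calls there.

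A change of at least 2-fold as well left 1216 calls at day 16, 1570 for time and 9 shared between the days. An adjusted p under 0.01 (limma) left 51, 1020, 31, 1517 and 477 calls at day 4, day 16, after knockdown, for time and for the difference, and overlaps of 3, 5, 2 and 13. With the day 4 labels exchanged, 60 genes were shared in the same direction between the days, and with the day 16 labels exchanged 5097 genes were called for time.

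Leaving out 1 array gave 28 to 142 calls at day 4, 908 to 3076 at day 16, 10 to 25 after knockdown, 1599 to 2679 for time and 584 to 2136 for the difference. The overlaps ran from 0 to 40, 3 to 32, 0 to 9 and 1 to 41, and LHX2 from 0.72 to 0.99 at day 16 and -2.40 to -1.66 after knockdown. Of 6777 values of named genes under the alternatives, 6223 were the same, 530 weaker, 24 stronger and 0 reversed. Most named genes were chosen because the main fit called them, so a reversal was unlikely from the start. A change of sign with no call in either fit was counted as the same. The counts also pool settings that differ little from the main fit.

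Camera called 1 list at day 4, 14 at day 16, 15 after knockdown, 16 for time and 14 for the difference. With an estimated correlation 1, 11, 8, 7 and 12 of these calls were lost. The rotation test fry lost the neuron list at day 4 and 5 lists after knockdown (neuron, surface ectoderm, BMP targets, Nodal and activin targets, Notch), and gained 4 at day 16, 4 for time and 2 for the difference. The series values lost 3 after knockdown and 5 for the difference, and gained 2 at day 4 and 1 for time. Median scaling lost 1 after knockdown and 3 for the difference, and gained 1 at day 4 and 2 at day 16. Cyclic loess lost 1 for time and gained 1 after knockdown. Without background correction 1 was lost and 1 gained after knockdown, and 1 was gained at day 16 and 2 for the difference. A replicate block lost 1 for the difference and gained 1 at day 16. In these runs 0 list calls reversed.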

Other observations

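The families, the permutation tests and the tests of explanations in this part were all chosen only after the result was seen. The p-values of the families come from the same arrays that led to the choice. They describe the families and give no independent support. The comparisons of dox at day 16 and of time share the dox-minus day 16 arrays. Opposite signs of a family in these comparisons are therefore not independent findings. Of 11 HOX genes, which set position along the body axis, limma called 9 lower in dox-plus cells at day 16. The median log2 fold change was -2.83, or -2.05 with genes below detection at their bound (camera adjusted p = 3.33e-13 over the families; adjusted p = 0.0513 with an estimated correlation). HOXC8 and HOXB7 were at least 14.3-fold and at least 3.52-fold lower, and HOXC6 fell by 3.14. Without the drug 9 of the 11 rose from day 4 to day 16, with a median of 2.85, or 2.12 at the bounds (camera adjusted p = 9.73e-11; adjusted p = 0.0513 with an estimated correlation). At day 4 no member was called (median 0.05; limma's camera, adjusted p = 0.515). After knockdown 1 member, HOXB2, was higher, and the median was 0.17, or 0 at the bounds (camera adjusted p = 0.0381; adjusted p = 0.453 with an estimated correlation).

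Of 9 metallothionein genes, which bind zinc and copper, limma called 2 higher in dox-plus cells at day 4, MT1G at 1.37 and MT1H at 1.62, with a family median of 0.76 (camera adjusted p = 1.48e-09; adjusted p = 0.0513 with an estimated correlation). At day 16, 6 of 9 fell, among them MT2A at -2.01, with a median of -0.96 (camera adjusted p = 6.58e-05; adjusted p = 0.131 with an estimated correlation). With time 8 of 9 fell (camera adjusted p = 6.35e-07; adjusted p = 0.0858 with an estimated correlation). After knockdown no member was called, at a median of 0.66 (camera adjusted p = 2.75e-09; adjusted p = 0.0513 with an estimated correlation). Of 32 collagen genes 16 fell and 2 rose at day 16, COL2A1 by 0.83 and COL9A1 by 1.40 (camera adjusted p = 1.74e-08; adjusted p = 0.131 with an estimated correlation). With time 17 rose and 4 fell (camera adjusted p = 1.17e-07; adjusted p = 0.14 with an estimated correlation). At day 4, 2 rose (camera adjusted p = 0.0381; adjusted p = 0.554 with an estimated correlation), and after knockdown 1 fell (camera adjusted p = 0.0413; adjusted p = 0.554 with an estimated correlation). Of 22 imprinted genes 4 rose and 4 fell at day 16, among them H19 upward, IGF2 downward and MEG3 by 2.10 upward (limma's camera, adjusted p = 0.277). With time 7 of them rose and 2 fell (camera adjusted p = 0.0108; adjusted p = 0.209 with an estimated correlation). The largest difference between replicates was that of SLC4A5 in shLHX2 cells, at 4.28 on 1 array and 10.43 on the other.

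Of the non-neural lists, camera called mesenchyme and mesendoderm lower in dox-plus cells at day 16, with mean log2 fold changes of -1.86 and -1.54. The means of endoderm, neural crest and surface ectoderm were -0.64, -0.35 and -0.35, and camera did not call these lists (adjusted p = 0.0608, 0.266 and 0.162). An equal fall of every non-neural cell type stays open. Permutation tests over genes, which are not independent, set the 5 means against each other with 100000 permutations. Their p was 0.00500 with all members, of which many lay too near the floor to fall. With members whose dox-minus signal lay at least 1, 2 or 3 above the lowest detected signal (log2), p was 0.0189, 0.0387 and 0.107. At 3, mesenchyme, mesendoderm, endoderm, neural crest and surface ectoderm kept 11, 5, 2, 9 and 3 members. Their means were then -1.93, -2.62, -1.39, -0.58 and -0.46. With so few members, a p of 0.107 does not show that the means are equal. A response to LHX2 alone stays open: the mesenchyme list had a median of -0.19 after knockdown (limma's camera, adjusted p = 0.364), and its members went both ways. A change in the share of a cell type was not tested.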
